A study of Drosophila melanogaster with 7 samples.

How the data were processed

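Tracheae of larvae in the third instar were profiled in 7 libraries, 4 control and 3 HopCA, made from poly(A) RNA with a stranded mRNA kit, per the labels' protocols. The authors deposited 1 gene table per library. Per the file headers, it holds raw read counts per gene (total and unique gene reads, exon reads, exon-exon reads and intron reads), an RPKM value, and gene and exon lengths. The deposited counts are whole numbers with no normalization, and total gene reads equal exon plus intron reads in every row. The deposited RPKM equals total exon reads scaled by exon length and by a library total slightly above the sum of gene reads, and was used only to check the counts. Reads had been trimmed with cutadapt 1.8.1 and the genome build was dm6, per the submitters' processing notes. The aligner and the counting program are not given in the sources used here, so how reads matching several genes were shared and whether strand was used are unknown. Counts of near-identical copies and of overlapping or antisense genes are therefore uncertain.

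Each table had 17697 rows with a gene name and 1 unnamed row with no reads, which was left out. 17657 rows matched a reference symbol (14106 by symbol, 3529 by synonym and 22 by position). 3784 rows have no exons, so that all their reads count as intron reads. Total gene reads were used. Their sums per library range from 16795748 to 20455268, 9.07% to 10.7% of which were not unique and 5.06% to 7.17% intronic. Groups were taken from the sample titles. No 2 libraries matched within sampling noise: the lowest chi-square per degree of freedom, over genes with at least 20 reads in a pair, was 20.6.

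Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr (minimum count 10, minimum total count 15), which left 9457. Libraries were scaled by TMM, and a model with the group as its only term was fitted with robust quasi-likelihood (glmQLFit, glmQLFTest). The biological coefficient of variation was 0.199. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. 54 gene lists were fixed before the data were examined, and the 53 with at least 5 measured members were tested with limma 3.58.1 camera, once with an inter-gene correlation preset at 0.01 and once with an estimated one, adjusted over the 53 lists. The text names genes by a rule fixed at the same time: hop first, then, among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, the 12 of highest and the 12 of lowest fold change, up to 4 members per list of the largest change among called ones (or the most expressed if none was called), and hop, Stat92E, dome, upd1, upd2, upd3 and Socs36E in any case. Some genes that the rule picks for the lists are left out of the text, so the members named need not be a list's largest changes. Any other named gene was chosen after its values were seen.

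Simulated counts for the same comparison were drawn from the measured means, library sizes and dispersions of 9457 genes, with 200 genes changed. In them, edgeR called 32.8% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 92.4% of those changed 4-fold. These were 22, 46 and 61 genes. A further 13 calls among the 9354 genes that passed the filter were false. The false share of all calls was thus above the adjusted threshold in that simulation. Whether the same holds for the data was not tested. In that simulation smaller changes were often missed. It held 200 changed genes where the data had 2978 called, which makes its adjusted threshold stricter, so the shares recovered may differ in the data.

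Alternatives fixed in advance were RLE size factors, library size only, no filter on low counts, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, unique gene reads, the replicate number as a block, the 20 most abundant genes left out, an adjusted p under 0.01, an estimated correlation and each library left out in turn. Exon reads, control replicate 2 and HopCA replicate 1 left out together, a muscle and a disc marker score as covariates and the JAK/STAT list without hop were added after seeing the data. The comparison was also repeated over all 35 splits of the 7 libraries into 4 and 3. Figures were drawn with matplotlib 3.10.9.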

Results

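The data are RNA sequencing counts from tracheae, the tubular airway epithelium, of Drosophila melanogaster larvae in the third instar. The series title asks how raised JAK/STAT signalling alters gene expression in airway epithelial cells. 4 libraries came from control animals, whose titles call them wild type, and 3 from animals expressing Hop.CA, named here HopCA. hop encodes the Drosophila JAK kinase, and Hop.CA is the form of it used here to raise JAK/STAT signalling. It was expressed under btl-Gal4, a driver active in the trachea, with the temperature-sensitive repressor Gal80ts. Control animals were kept at 18 °C. HopCA animals were kept at 18 °C and moved to 29 °C at the second larval stage for 18 hours before sampling. Hop.CA expression and temperature therefore changed together, and no library separates them, so every difference below is between the 2 groups as they were reared. Stage within the third instar, which temperature also affects, is not given and was not compared. The strain label is the same for all 7 libraries and names the Hop.CA transgene also for the controls. The titles number the libraries as biological replicates, with no statement on how many animals each pool held. Reads assigned to genes numbered 19174963, 20455268, 16795748 and 20200900 in control replicates 1 to 4, and 18618125, 19467116 and 19597298 in HopCA replicates 1 to 3. Values below are CPM, counts scaled to each library's normalised size, as mean ± SD, with n = 4 control and n = 3 HopCA libraries. Fold changes are log2 values of HopCA over control with their standard errors (SE), and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 9457 genes. The SE were computed back from that test, as the absolute log2 fold change over the square root of its F statistic.

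The groups differed widely. 2978 of 9457 tested genes (31.5%) changed at adjusted p 0.05, of which 1547 were higher and 1431 lower in HopCA, and 842 changed at least 2-fold. Secretory pathway genes, hop, dome, Socs36E and the peptide gene Drs were among the higher genes, and mitotic, muscle, cuticle and ribosome biogenesis genes were among the lower ones. The libraries of the 2 groups did not overlap for 4095 genes (43.3%), against 5.71% expected by chance for 4 against 3. The first principal component held 54.0% of the variance and parted the groups, while on the second (16.96%) control replicate 2, at -34.3, stood apart from the other controls, at 8.41 to 16.8, and HopCA replicates 1 to 3 were spread over -20.1, 21.8 and -3.12. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.969 to 0.986 within control, 0.979 to 0.985 within HopCA and 0.938 to 0.957 between groups. The count of changed genes was 1829 without HopCA replicate 1 and 1676 without HopCA replicate 3. It was 1573 without control replicate 2 and HopCA replicate 1 together, a choice made after seeing the data.

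**Figure D1:**
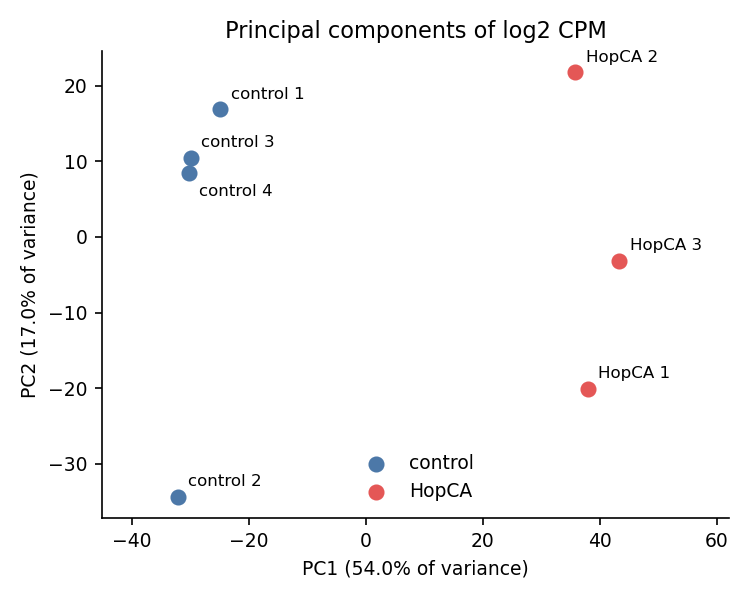
Principal components of log2 CPM of the 9457 tested genes, PC1 on the x axis (54.0% of the variance) and PC2 on the y axis (16.96%), 1 point per library, blue for control and red for HopCA. The groups part on PC1, control replicate 2 lies apart from the other controls on PC2, and the HopCA replicates are spread along it.

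**Figure D2:**
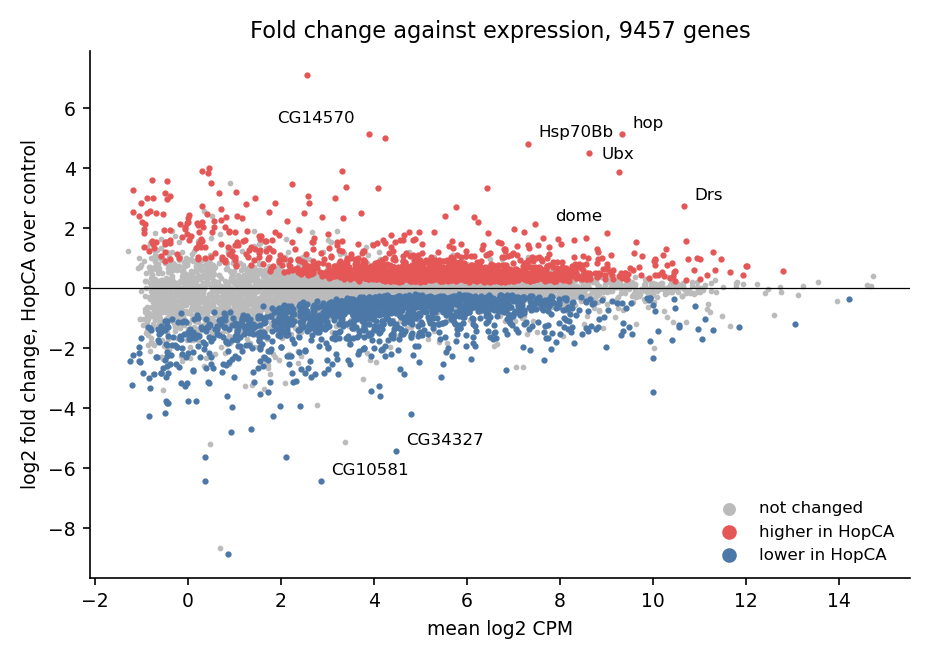
Log2 fold change of HopCA over control (y axis) against mean log2 CPM (x axis), 1 point per tested gene, red for the 1547 higher genes, blue for the 1431 lower ones and grey for genes that did not pass adjusted p 0.05. hop lies at 5.14, Drs at 2.73 and CG10581 at -6.41.

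The targeted gene was read first. hop rose from 41.5 ± 2.64 to 1459.6 ± 126 CPM, a log2 fold change of 5.14 ± 0.103 (SE, adjusted p = 2.69e-07). Its exon-exon reads, which span a splice junction, rose with its exon reads. dome, the receptor upstream of the kinase, rose from 102 ± 19.2 to 327 ± 12.01 CPM (log2 1.68 ± 0.147, adjusted p = 4.87e-04). Socs36E, a negative feedback target of the pathway, rose from 91.6 ± 15.9 to 249 ± 19.9 CPM (log2 1.44 ± 0.144, adjusted p = 6.81e-04). The transcription factor gene Stat92E stood at 149 ± 13.4 and 172 ± 3.78 CPM and did not pass the test (log2 0.21 ± 0.0864, adjusted p = 0.102). Its libraries did not overlap between the groups, as for 43.3% of all tested genes. The ligand genes upd1, upd2 and upd3 were near the floor, with 0.539, 0.458 and 0.9799 CPM in HopCA, and none passed (adjusted p = 0.0635, 0.416 and 0.593). Of 18 measured pathway components, 5 rose and 1 fell, with 6 called when adjusted over the list alone, and the list had a camera adjusted p of 0.000194, or 0.911 with an estimated correlation. Without hop, a choice made after seeing the data, the camera adjusted p was 0.175 and the median log2 fold change 0.09. The full list lost its call without control replicate 1 (0.110) and with limma-voom (0.109). Of 19 STAT-responsive genes, 6 rose, among them Tep4, a thioester-containing protein gene (log2 0.98 ± 0.176), and 3 fell, among them nab (log2 -1.39 ± 0.288), with 9 called when adjusted over the list alone and a camera adjusted p of 0.175. TotA, of the Turandot stress genes, was at 15.3 ± 14.7 and 9.13 ± 5.13 CPM and did not pass (log2 -0.74 ± 0.749, adjusted p = 0.4797). Too few Turandot genes were measured to test that list.

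**Figure D3:**
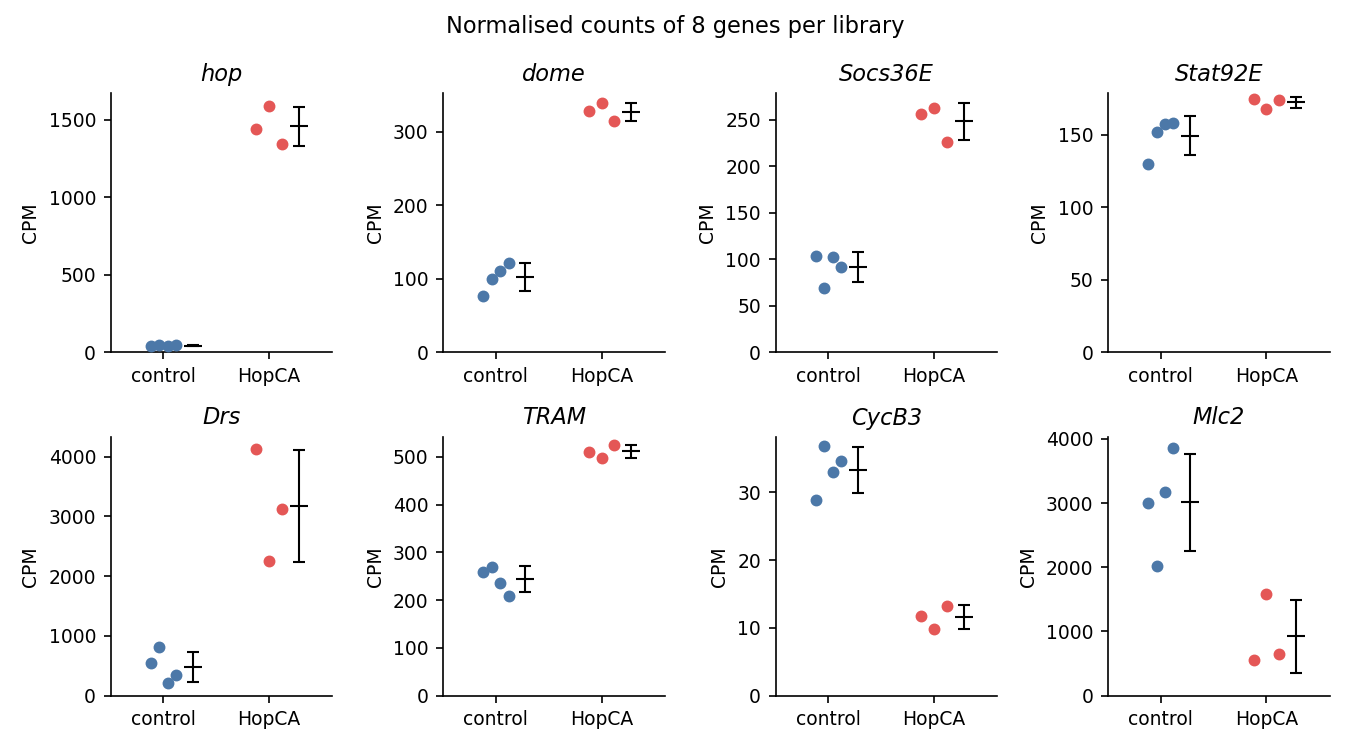
CPM of 8 genes (y axes, each starting at 0) in the 4 control (blue) and 3 HopCA (red) libraries, 1 point per library, with the mean and SD as a black bar beside them. hop, dome, Socs36E, Drs and TRAM are higher and CycB3 and Mlc2 lower in every HopCA library. Stat92E is also higher in every HopCA library, with means of 149 CPM in control and 172 in HopCA, but did not pass the test.

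**Figure D4:**
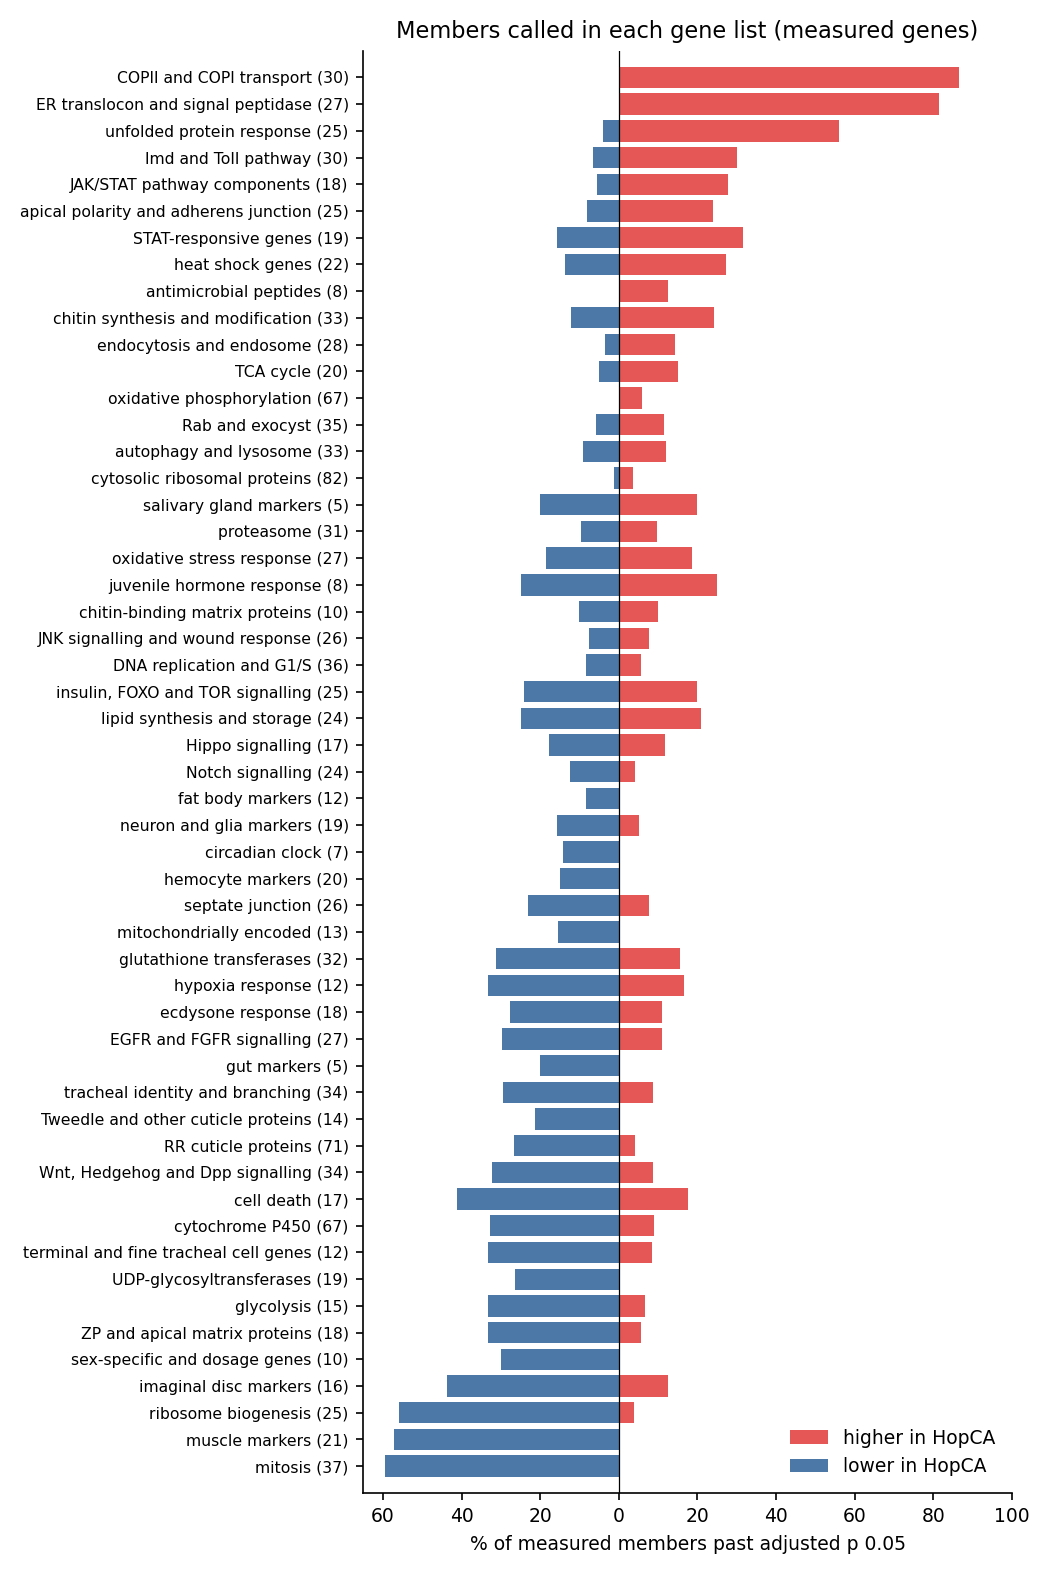
Percent of the measured members of each of 53 gene lists (number measured in brackets) past adjusted p 0.05, higher in HopCA to the right in red and lower to the left in blue. COPII and COPI transport, with 26 of 30 higher, lies at the top and mitosis, with 22 of 37 lower, at the bottom.

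Genes of the early secretory pathway formed the group with the highest share of higher members. Of 30 measured genes of COPII and COPI vesicle transport, 26 rose and none fell, including ergic53, a cargo receptor (log2 0.80 ± 0.0695), garz, an Arf exchange factor (log2 0.78 ± 0.1396), the COPII coat gene Sec31 (log2 0.73 ± 0.151) and CrebA, a transcription factor of secretory genes (log2 0.68 ± 0.1402). The median log2 fold change was 0.52, 26 members were called when adjusted over the list alone, and the camera adjusted p was 1.01e-09, or 0.0392 with an estimated correlation. Of 27 genes of the endoplasmic reticulum translocon and signal peptidase, 22 rose and none fell, with TRAM from 244 ± 27.00 to 511 ± 14.3 CPM (log2 1.07 ± 0.0997) and Sec61beta at log2 0.87 ± 0.108. 23 were called when adjusted over the list alone, and the camera adjusted p was 2.00e-07, or 0.911 with an estimated correlation. Of 25 unfolded protein response genes, 14 rose and 1 fell. The chaperone gene Hsc70-3 (BiP) rose from 801 ± 71.2 to 1385 ± 65.1 CPM (log2 0.79 ± 0.0922) and crc, the fly ATF4, by log2 0.77 ± 0.0773. 17 were called when adjusted over the list alone, and the camera adjusted p was 0.000194, or 0.782 with an estimated correlation. Of 28 endocytosis and endosome genes 4 rose and 1 fell (2 called when adjusted over the list alone), and of 35 Rab and exocyst genes 4 rose and 2 fell, with camera adjusted p of 0.471 for both. The lists were not tested against each other.

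Immune genes did not move as one group. Drs, which encodes the antifungal peptide drosomycin, rose from 479 ± 257 to 3170.4 ± 939 CPM (log2 2.73 ± 0.451, adjusted p = 0.00555), and the other 7 of 8 measured antimicrobial peptide genes did not pass. Of 30 Imd and Toll pathway genes, 9 rose and 2 fell, with 11 called when adjusted over the list alone. Dif, a Toll pathway NF-kappaB factor, rose by log2 1.12 ± 0.0799, and the kinase gene pll by log2 0.64 ± 0.0973. PGRP-SA, a peptidoglycan sensor of that pathway, fell from 69.5 ± 11.4 to 12.1 ± 4.92 CPM (log2 -2.52 ± 0.271, adjusted p = 0.00107). The camera adjusted p was 0.410 for the peptides and 0.175 for the pathway list.

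Among genes with a mean log2 CPM of at least 1 whose libraries did not overlap, the 12 with the highest fold change were CG16772, CG14570, hop, CG14147, Hsp70Bb, Ubx, IM4, CG14569, CG9121, CG11413, CG31960 and CR31958. CG14570 (3L, 21729675 to 21730454, dm6) rose by log2 5.15 ± 0.458 and its neighbour CG14569 (3L, 21730725 to 21731550) from 89.9 ± 58.9 to 1312 ± 533 CPM, and CG31960 and CR31958, which adjoin on 2L (3784947 to 3785622 and 3785738 to 3786343), rose by log2 3.33 ± 0.106 and 3.32 ± 0.118. CG16772 was at 1.798, 36.3 and 2.53 CPM in the HopCA replicates, so its mean rests mainly on replicate 2. Ubx, a Hox gene, rose from 38.5 ± 2.69 to 875 ± 59.97 CPM (log2 4.51 ± 0.0957, adjusted p = 2.69e-07), while its exon-exon reads numbered 27 to 38 per control library and 29 to 39 per HopCA library. Hsp70Bb rose from 12.6 ± 3.54 to 353 ± 19.7 CPM (log2 4.81 ± 0.208), and by uniquely assigned reads from 7 to 33 per control library to 4995 to 5413 per HopCA library. The 12 lowest were CG10581 (3L, 21033554 to 21034203), phm, CG34327, Ucp4B, GstD6, CG13639, CG5866, pre-mod(mdg4)-AD, CG9509, CG15485, CR30029 and CG7888. CG10581 fell from 12.4 ± 2.06 to 0.139 ± 0.0282 CPM (log2 -6.41 ± 0.249, adjusted p = 1.25e-05) and CG34327 from 38.03 ± 9.64 to 0.882 ± 0.296 CPM (log2 -5.41 ± 0.299). phm, an ecdysone synthesis enzyme gene, had 7.12 ± 11.3 CPM in control, with 24.1 in replicate 2, against 0.1399 ± 0.0337 in HopCA. CG11413, phm, CG5866, pre-mod(mdg4)-AD and CG15485 lost the call when a single library was left out, CG11413 without control replicate 2, 3 or 4 or HopCA replicate 2 or 3 (adjusted p 0.0615 to 0.143), CG5866 without control replicate 2 or any HopCA library (0.0550 to 0.110), pre-mod(mdg4)-AD without control replicate 1, 3 or 4 or HopCA replicate 1 or 3 (0.0522 to 0.0655), CG15485 without HopCA replicate 2 or 3 (0.0644 and 0.0756) and phm without any 1 HopCA library (0.125 to 0.139), and phm fell under the expression filter without control replicate 2, 3 or 4 and did not pass with limma-voom (adjusted p 0.229), so its fall is uncertain. Without HopCA replicate 2 the log2 fold change of CG16772 was 4.47 in place of 7.11 and that of IM4 2.57 in place of 3.91. Ucp4B has no uniquely assigned read, so its fall is uncertain.

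**Figure D5:**
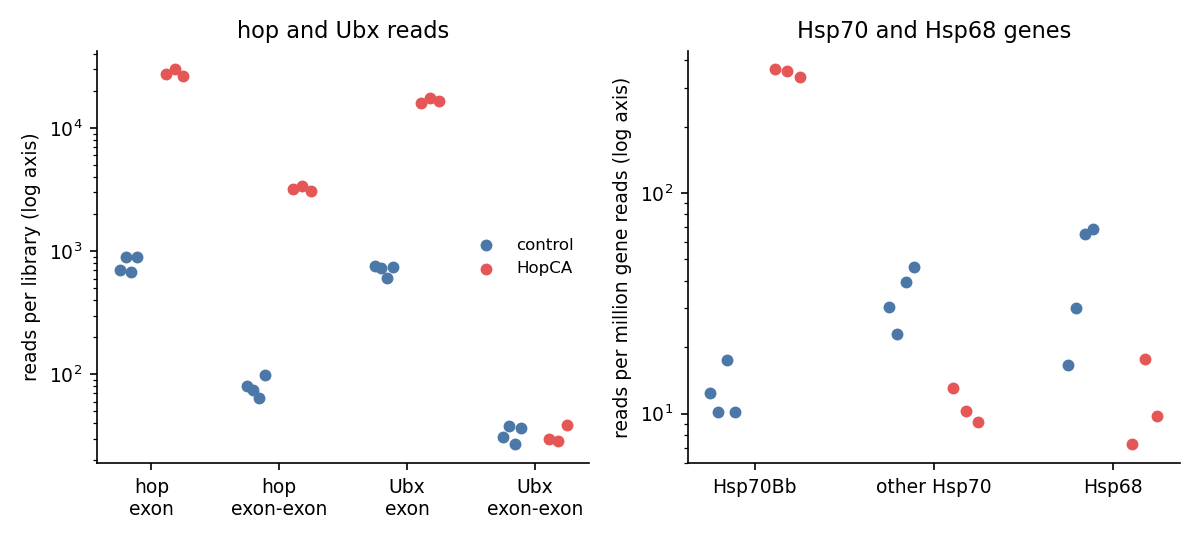
Left, exon reads and exon-exon reads of hop and Ubx per library (y axis, log scale) in control (blue) and HopCA (red). hop rises in both kinds of read and Ubx in exon reads alone, with exon-exon reads of 27 to 38 in control and 29 to 39 in HopCA. Right, CPM relative to all gene reads (log scale) of Hsp70Bb, of the 5 other Hsp70 genes summed and of Hsp68.

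Among cuticle genes more fell than rose. Of 71 RR cuticle proteins, which bind chitin, 19 fell and 3 rose. Cpr65Au fell from 179 ± 31.6 to 27.5 ± 19.7 CPM (log2 -2.71 ± 0.642) and Cpr49Ah also fell (log2 -1.96 ± 0.249), while Lcp65Ad rose by log2 2.55 ± 0.305. 22 were called when adjusted over the list alone, with a camera adjusted p of 0.000234, or 0.911 with an estimated correlation, and 0.255 with the muscle score as a covariate, a choice made after seeing the data. Of 14 Tweedle and other cuticle proteins 3 fell (1 called when adjusted over the list alone), among them TwdlT (log2 -2.26 ± 0.316), of 10 chitin-binding matrix proteins 1 rose and 1, obst-B, fell (log2 -1.51 ± 0.203), and of 18 ZP and apical matrix genes 6 fell, among them tyn (log2 -1.26 ± 0.357), and 1 rose. Of 33 genes of chitin synthesis and modification 8 rose and 4 fell. The tracheal chitin deacetylase gene serp rose from 3208 ± 194 to 5373 ± 155 CPM (log2 0.74 ± 0.0782), and Idgf3 rose by log2 0.68 ± 0.102. That list had a median of 0.01 and a mean of -0.03. Camera adjusted p for these 4 lists was 0.175, 0.333, 0.118 and 0.8287. tyn, whose libraries overlap between the groups, lost its call in 12 of 21 settings, among them without control replicate 1, 3 or 4 or any 1 HopCA library (adjusted p 0.0605 to 0.0989).

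Airway epithelial genes moved both ways. Of 34 tracheal identity and branching genes 10 fell and 3 rose. btl, the FGF receptor gene whose driver expresses Hop.CA, fell from 108 ± 18.5 to 69.6 ± 6.45 CPM (log2 -0.63 ± 0.142, adjusted p = 0.0138), and rho, an EGFR ligand protease gene, fell too (log2 -1.33 ± 0.162). Of 12 terminal and fine tracheal cell genes 4 fell and 1 rose, with bs at log2 -0.54 ± 0.139. Of 26 septate junction genes 6 fell and 2 rose, with Lac at log2 -0.63 ± 0.0745, and of 25 apical polarity and adherens junction genes 6 rose and 2 fell, with sqh, the myosin regulatory light chain, at log2 0.67 ± 0.113. Camera adjusted p for these 4 lists was 0.193, 0.175, 0.311 and 0.353. btl lost its call without HopCA replicate 1 (adjusted p 0.0512) and bs without HopCA replicate 1 or 2 (0.0774 and 0.0527).

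Most of the mitotic genes fell. Of 37 mitosis genes 22 fell and none rose, with CycB3, a B-type cyclin, from 33.3 ± 3.37 to 11.6 ± 1.77 CPM (log2 -1.52 ± 0.1298), borr at log2 -1.19 ± 0.127 and aurA at log2 -1.09 ± 0.218. 25 were called when adjusted over the list alone, the median log2 fold change was -0.78, and the camera adjusted p was 2.26e-07, or 0.926 with an estimated correlation. With a disc marker score as a covariate, a choice made after seeing the data, the median was -0.23 and the camera adjusted p 0.151. In the same libraries muscle markers had a median of -1.26 and imaginal disc markers of -1.30. Of 36 DNA replication and G1/S genes 2 rose and 3 fell (4 called when adjusted over the list alone), with RnrL at log2 -0.42 ± 0.0734 and a camera adjusted p of 0.722. Of 25 ribosome biogenesis genes 14 fell and 1 rose, with nop5 at log2 -0.73 ± 0.0728 and Nop60B at log2 -0.65 ± 0.0855. 17 were called when adjusted over the list alone, and the camera adjusted p was 0.00824, or 0.911 with an estimated correlation. It was 0.0659 without HopCA replicate 2. Of 17 cell death genes 7 fell and 3 rose, with Buffy at log2 -1.14 ± 0.0757, rpr at log2 -1.09 ± 0.175 and hid at log2 -1.04 ± 0.3098 (camera adjusted p = 0.277). hid lost its call in 10 of 21 settings, among them without control replicate 2, 3 or 4 or HopCA replicate 2 or 3 (adjusted p 0.0552 to 0.0924).

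Signalling lists other than JAK/STAT had no camera call. Of 34 Wnt, Hedgehog and Dpp genes 11 fell and 3 rose, with wg at log2 -1.44 ± 0.317 and dpp at log2 -0.99 ± 0.244. Of 27 EGFR and FGFR genes 8 fell and 3 rose, with grk at log2 -1.83 ± 0.239, of 24 Notch genes 3 fell and 1 rose, with Tom at log2 -1.43 ± 0.353, and of 17 Hippo genes 3 fell and 2 rose, with Diap1 at log2 -0.39 ± 0.0695. Of 26 JNK and wound genes 2 rose and 2 fell, with scaf at log2 1.10 ± 0.2804. Adjusted over the list alone, 2 Notch genes and 1 JNK and wound gene were called. Of 25 insulin, FOXO and TOR genes 5 rose and 6 fell, with a median of 0.03 and a mean of -0.01. ImpL2, which encodes a secreted insulin-binding protein, rose from 106 ± 8.39 to 288 ± 50.3 CPM (log2 1.44 ± 0.127) and the translation inhibitor gene Thor by log2 0.73 ± 0.207. Camera adjusted p for these 6 lists was 0.103, 0.175, 0.175, 0.756, 0.577 and 0.839. Calls were lost for wg and Tom without HopCA replicate 3 (adjusted p 0.0536 and 0.0700), for dpp without HopCA replicate 1 or 2 (0.0740 and 0.0655), for scaf without HopCA replicate 2 or 3 (0.0646 and 0.0719) and for Thor without control replicate 2 or 3 or any 1 HopCA library (0.0539 to 0.1003).

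Stress, hormone and detoxification lists were mixed. Of 22 heat shock genes 6 rose and 3 fell, with Hsp70Bb higher and Hsp70Ab lower (log2 -2.24 ± 0.591), the latter uncertain because near-identical copies share reads. The median of the list was -0.03 and the mean -0.12 while camera ranked it upward (adjusted p = 0.200). Of 18 ecdysone response genes 5 fell, with Eip74EF at log2 -0.62 ± 0.197, and 2 rose (camera adjusted p = 0.277), and of 8 juvenile hormone genes 2 rose and 2 fell (0.864). Of 67 cytochrome P450 genes 22 fell and 6 rose, with Cyp6a2 at log2 -2.44 ± 0.351 and Cyp4d21 at log2 2.41 ± 0.337, and the camera adjusted p was 0.00541, or 0.926 with an estimated correlation. With a muscle marker score as a covariate, a choice made after seeing the data, the median of that list turned from -0.42 to 0.02. Of 32 glutathione transferases 10 fell and 5 rose, with GstT4 at log2 -1.92 ± 0.155 and GstD9 at log2 1.86 ± 0.174, and of 19 UDP-glycosyltransferases 5 fell, with a median of 0.10, a mean of -0.03 and camera ranking it downward. Of 27 oxidative stress genes 5 rose and 5 fell, with catalase (Cat) at log2 0.98 ± 0.133, a median of 0.03, a mean of -0.15 and camera ranking it upward. Camera adjusted p for these 3 lists was 0.277, 0.722 and 0.839. Of 12 hypoxia genes 4 fell and 2 rose, with ImpL3 (lactate dehydrogenase) at log2 -1.14 ± 0.305 (camera adjusted p = 0.471), and of 7 clock genes 1, cyc, fell (0.680). Eip74EF lost its call in 11 of 21 settings, among them without control replicate 1, 3 or 4 or any 1 HopCA library (adjusted p 0.0550 to 0.138), Hsp70Ab without control replicate 3 or 4 or HopCA replicate 3 (0.0603 to 0.0665), ImpL3 without control replicate 3 or 4 or HopCA replicate 1 or 3 (0.0565 to 0.0985) and cyc without HopCA replicate 2 or 3 (0.0513 and 0.0626).

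Metabolic and housekeeping lists had no camera call. Of 24 lipid genes 5 rose and 6 fell. Hmgs rose by log2 0.79 ± 0.103 and FASN2 by log2 2.39 ± 0.414, and the lipid droplet gene Lsd-1 fell (log2 -1.55 ± 0.313). Of 15 glycolysis genes 5 fell and 1, Hex-A, rose (log2 1.15 ± 0.116), of 20 TCA cycle genes 3 rose and 1 fell, and of 67 oxidative phosphorylation genes 4 rose, with 3 and none called when adjusted over the list alone. Of 13 mitochondrially encoded genes 2 fell, with lrRNA at log2 -0.37 ± 0.0811, not called without HopCA replicate 2 or 3 (adjusted p 0.0623 and 0.0669). Of 82 ribosomal protein genes 3 rose and 1 fell, of 31 proteasome genes 3 rose and 3 fell, and of 33 autophagy and lysosome genes 4 rose, with Atg1 at log2 1.12 ± 0.1604, and 3 fell, with a median of -0.02 and a mean of 0.02. Adjusted over the list alone, none of the ribosomal protein genes, 5 of the proteasome and 6 of the autophagy and lysosome genes were called. Camera adjusted p for these 8 lists, in the order given, was 0.556, 0.277, 0.775, 0.277, 0.420, 0.880, 0.889 and 0.993.

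Among markers of other cell types, those of muscle had the highest share of lower members. Of 21 muscle markers 12 fell and none rose, with Mlc2 from 3015 ± 756 to 926 ± 566 CPM (log2 -1.70 ± 0.417) and Act87E at log2 -1.81 ± 0.367. 17 were called when adjusted over the list alone, and the camera adjusted p was 5.32e-05, or 0.926 with an estimated correlation. The mean log2 CPM of the muscle markers was 6.76 and 7.14 in HopCA replicates 1 and 3. In HopCA replicate 2 it was 8.17, within the control range of 8.15 to 9.07. Of 16 imaginal disc markers 7 fell, with nub at log2 -1.64 ± 0.432 and vg at log2 -1.54 ± 0.433, and 2 rose, ey and, in exon reads but not in exon-exon reads, Ubx. Of 19 neuron and glia markers 3 fell, with Gs2 at log2 -1.38 ± 0.317, and 1 rose. Of 20 hemocyte markers 3 fell, with atilla at log2 -0.82 ± 0.09199, of 12 fat body markers 1 fell (none called when adjusted over the list alone), of 5 gut markers 1 fell, and of 5 salivary gland markers 1 rose and 1 fell. Of 10 sex-specific and dosage genes 3 fell, with kl-5, a Y-linked dynein gene, at log2 -1.29 ± 0.273. Camera adjusted p for the 7 lists after muscle was 0.778, 0.471, 0.175, 0.441, 0.277, 0.700 and 0.275. Calls were lost for Mlc2 without HopCA replicate 1 or 3 (adjusted p 0.0577 and 0.0768), for nub and vg without control replicate 3 or HopCA replicate 2 or 3 (0.0570 to 0.103) and for Gs2 without HopCA replicate 1 (0.0560).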

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

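The tests of Ubx and Hsp70Bb below and all comparisons with other splits of the libraries were chosen after the results were seen; the covariate tests were set out before their results were computed, except for the reading of the muscle score by camera.

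The change counts were checked against the other splits of the 7 libraries into 4 and 3. The real grouping was the only 1 of 35 to reach 2978 changed genes (highest other 7), 1547 higher (7), 1431 lower (2) or 842 changed at least 2-fold (6). Every other split puts control and HopCA libraries together in at least 1 group. The difference between them then adds to the spread and keeps the counts low. The check therefore cannot exclude chance, and 1 of 35 is the smallest share it can give. The number of gene lists called by camera with the preset correlation did not set the real grouping apart. 30 of the 35 splits called at least its 9 lists, up to 29, so that number is no evidence of an effect. List by list, camera p was smallest in the real split for COPII and COPI transport, JAK/STAT components and the unfolded protein response. With 53 lists ranked over 35 splits, some first places arise by chance, so a first place alone is weak support. The JAK/STAT list includes hop, the gene expressed on purpose, so its place was largely set by the design. Without hop its camera adjusted p was 0.175, and the splits were not run that way. With an estimated correlation the JAK/STAT and unfolded protein response lists had camera adjusted p of 0.911 and 0.782. Of the other called lists, as small a p came from 5 of the 35 splits for the ER translocon and signal peptidase, 6 for ribosome biogenesis, 12 for mitosis and 13 each for muscle markers, RR cuticle proteins and cytochrome P450 genes.

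Ubx exon reads per exon-exon read, a measure the report's tests did not use, had a median of 528.3 in HopCA against 19.1 to 24.7 in control libraries. Exon reads rose by 4.55 on the log2 scale while exon-exon reads, 133 in control and 98 in HopCA, changed by -0.031 (95% exact interval -0.42 to 0.36 for counting error alone, and -0.49 to 0.42 from the spread between libraries), which argues against more spliced Ubx mRNA. The excess of exon over exon-exon change, 4.57, exceeded that of every other one of 5456 genes with at least 100 exon-exon reads, the next being 1.13. Intron reads, 25 to 31 per control and 76 to 92 per HopCA library, rose by 1.59 (95% interval over libraries 1.28 to 1.90), which argues against unspliced RNA of the whole gene as the cause. Hsp70Bb rose while the other Hsp70 copies and Hsp68 together fell by 1.83 on the log2 scale. How reads of near-identical copies were shared is unknown, so the fall of the other Hsp70 copies is uncertain. Hsp68 fell too (log2 -1.93, edgeR adjusted p = 0.0407). Its libraries overlapped between the groups, at 16.6 CPM in control replicate 1 and 17.7 in HopCA replicate 2. Of 22 heat shock genes 6 rose and 3 fell, with Hsp22 at log2 2.27 and Hsp23 at log2 1.87. Heat induction at 29 °C is therefore not excluded as the source of the Hsp70Bb reads. A candidate explanation, fitted by the Ubx value, is that both genes' extra reads come from unspliced pieces of Ubx and Hsp70Bb sequence carried by a transgene expressed with hop; the construct's sequence was not used here, and an endogenous Ubx RNA that lies within an exon stays open.

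Mitotic genes fell (median -0.78) in libraries that also had lower muscle and disc markers. With the disc score, taken without Ubx, as a covariate, the median was -0.23 (bootstrap interval over members -0.34 to -0.07), within the bound set for fewer attached disc cells being the cause, although the interval crosses that bound. 4 of 37 members were still called lower, against 446 of all 9457 genes. With the muscle score it was -0.70 (-0.90 to -0.45), past the -0.26 that the cause needs, but the stricter bound of -0.52 set beforehand was not met. Both intervals resample members and not libraries. The members move together (estimated correlation 0.595 without a covariate), so the intervals are too narrow. Camera with the preset correlation still called the list (adjusted p 4.58e-05), a call that without a covariate was lost at the estimated correlation (0.926). The muscle list itself went from -1.26 to -0.09, which follows from its use as the covariate. 3 of 37 members were still called lower, in place of 22, against 356 of all 9457 genes. That fit had a residual degree of freedom fewer and a score tied in part to the group, and both reduce calls. The muscle score thus took little off the median, but the test does not decide whether fewer muscle cells were the cause. By the disc score, fewer disc cells may account for much of the fall, but disc markers and mitotic genes could both be lower for a reason tied to the group, which the covariate would also absorb. The biological explanation, less division of tracheal cells with Hop.CA, at the higher temperature or at another stage, was not tested.

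The COPII and COPI list rose by a median of 0.52. With the muscle score as a covariate it was 0.49 (bootstrap interval over members, not libraries, 0.40 to 0.56), which argues against less dilution by muscle RNA as the whole cause. However, 7 of 30 members were still called higher in place of 26, against 401 of all 9457 genes. That fit had a residual degree of freedom fewer and a score tied in part to the group, and both reduce calls. Whether Hop.CA or the move to 29 °C raised these genes cannot be told from this design. A response of the secretory pathway to either remains a hypothesis.

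A control library far from the other 3 was found for 10 of 117 values tested, and chance flags about 1 in 20. The values are not independent, so these shares cannot be compared directly. Control replicate 2, which stood apart on the second principal component, was flagged more often than any other control library. CG9121 was at 0.416 CPM in control replicate 3 against 0.966 to 1.06 in the others. phm was at 24.1 CPM in control replicate 2 against 0.483 to 2.02 in the others. GstD6 was at 11.5 CPM in control replicate 2 against 2.95 to 4.403 in the others. CG7888 was at 51.05 CPM in control replicate 2 against 12.2 to 18.8 in the others. nab was at 8.65 CPM in control replicate 4 against 4.51 to 5.06 in the others. Eip74EF was at 198 CPM in control replicate 2 against 121 to 125 in the others. garz was at 41.9 CPM in control replicate 1 against 61.4 to 61.8 in the others. Sec31 was at 88.9 CPM in control replicate 1 against 135 to 137 in the others. CG32564 was at 261 CPM in control replicate 2 against 396 to 403 in the others. CG32563 was at 0.632 CPM in control replicate 4 against 0.161 to 0.2399 in the others.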

How the results depend on the processing

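hop was higher at every setting run, by log2 5.07 to 5.26 with adjusted p of at most 0.00186. The median of all genes stayed within 0.031 of 0 on the log2 scale, and RLE (2960 genes), library size only (2895), no filter (2711), the CPM filter (2880), DESeq2 (3342), limma-voom (2942), unique reads (2758), no top 20 genes (2968) and exon reads (2915, added after seeing the data) kept the count of changed genes within 1.5 times of 2978. Of the 24 genes of largest change, 15 were still called with the replicate block and 15 with the disc score. At adjusted p 0.01, 1312 genes were called.

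Leaving out 1 library moved the changed genes to between 1676 and 3407, the higher ones to between 938 and 1753, the lower ones to between 738 and 1654, those changed 2-fold to between 575 and 832, the called lists to between 9 and 14 and the called ones of those 24 genes to between 19 and 23. The cause was not tested beyond the smaller number of libraries. Of 109 genes named in the text and called, 26 lost the call with at least 1 library left out. Of those besides hop, 43 of 107 lost it with the replicate block, 43 of 108 with the muscle score and 55 of 108 with the disc score. With unique reads only 98 of the 108 were fitted, and 95 of these kept their call. The others, Ucp4B among them, could not be checked that way. Without control replicate 2 and HopCA replicate 1, which was added after seeing the data, 1573 genes changed, 838 higher and 735 lower, and 8 lists were called. With the muscle score as a covariate, also added later, 757 changed (401 higher, 356 lower, 418 at least 2-fold), and with the disc score 871 (425, 446 and 400). Each covariate uses up a residual degree of freedom. The disc score, taken without Ubx, was 2.20 to 3.34 in control and 1.43 to 1.96 in HopCA libraries, with no overlap. The muscle score overlapped only through HopCA replicate 2. A score tied to the group widens the error of the group term, so fewer calls follow in part from the covariate itself. How much of the loss this makes was not tested.

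No sign was found that the replicate numbers pair the samples: deviations of same-numbered libraries correlated at -0.22, -0.43 and -0.07, and no HopCA library correlated best with its own number. Other differences between libraries could hide a smaller shared effect, so pairing is not excluded. With the number as a block on replicates 1 to 3, 1002 genes changed (530 higher, 472 lower, 378 at least 2-fold), against 2479 for the same libraries without the block. With an estimated correlation 1 list, COPII and COPI transport, was called in place of 9. With the muscle covariate the cytochrome P450 median reversed to 0.016, upd2 reversed to -1.06 with the disc covariate and TotA, between -1.29 and 0.15 with 1 library left out, without control replicate 1; the cause was not tested. Depth limits genes near the floor such as upd1, upd2 and upd3.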

Other observations

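The tests of reads shared between copies and between overlapping genes, and the choice of the peptide genes named next, were made after the values were seen. Several genes of small secreted peptides known as targets of the Toll pathway were called higher in HopCA; no list of them was tested. IM1, IM2 and IM3 (now BomS1, BomS2 and BomS3), which adjoin on 2R, rose by log2 3.50 ± 1.002, 3.83 ± 0.825 and 2.39 ± 0.722 (edgeR adjusted p = 0.0341, 0.0119 and 0.0401), CG5778 (BomT3) by 2.75 ± 0.646 and CG5791 (BomBc3) by 3.91 ± 0.972. IM4 (Dso1) rose by log2 3.91 ± 0.855 and its neighbour IM14 (Dso2) by 3.99 ± 0.687. Except for IM4, at 21.05 CPM in HopCA, these were at 2.21 to 3.10 CPM there, and IM4 varied between libraries, at 13.5, 46.6 and 3.03 CPM. Several of these calls are weak. IM1 lost its call in 9 of 20 settings, among them without any 1 control library or HopCA replicate 2 (adjusted p 0.0520 to 0.123), IM3 in 10 of 21, among them without control replicate 1, 3 or 4 or HopCA replicate 1 or 2 (0.0538 to 0.141), and CG5791 in 8 of 18, among them without any 1 control library (0.0509 to 0.0543). Without HopCA replicate 2 the log2 fold changes of IM1, CG5778, CG5791 and IM4 were 1.95, 1.73, 1.95 and 2.57. With the disc score as a covariate none of the 7 was called (adjusted p 0.135 to 0.564). That score did not overlap between the groups, so this loss follows in part from the covariate itself.

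Genes that changed at least 2-fold lay next to each other more often than chance gives. Among the 842 such genes, 93 adjacent pairs of tested genes changed in the same direction, against a median of 42 and at most 67 in 10000 random orders within chromosomes (permutation p = 1e-04, one-sided, the smallest that number of orders can give). Without overlapping pairs it was 80 against a median of 34 and at most 57 (permutation p = 1e-04, again the smallest possible). Of the 165 genes in such pairs, 17 (10.3%) lost over 0.5 of their log2 change or all of their reads when unique reads alone were counted, 13 of them having no unique read, which argues against shared reads as the main source. Runs included CG13043, CG13063, CG13042, CG13041 and CG13060 on 3L, called lower (CG13041 has 1 unique read of 229, so its fall is uncertain), and CG32564, CG32563, CG12995, CG18258 and CG5162 on X, called higher. Shared regulation of neighbouring genes is a possible explanation, and a different strain background in the 2 groups, which would also act by region, was not tested.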
